A study of Homo sapiens with 6 samples.

How the data were processed

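The series holds 6 arrays of total RNA from NCI-H292 cells, 3 of cells stably transfected with CT45A1 joined to Venus (CT45A1 overexpression) and 3 of cells with the Venus vector (CT45A1 negative). Groups and replicate numbers were taken from the sample titles. RNA was labelled with a kit for 3' expression arrays, per the labels' protocols. The deposited values are MAS5 signals, a linear intensity for each of 54675 probe sets on each array, made with MAS5 and the affy package per the submitters' processing notes, with versions not given in the sources used here. The 2% trimmed mean of the deposited intensity was 500.1 on every array, so the arrays had been brought to a common mean. Such scaling leaves the medians free to differ, and the mean log2 array median was 0.145 higher in the overexpression group. Detection calls were not used here, so dim signals carry no statement of presence. The share of probe sets with a signal under 32 ranged from 31.1% to 33.6% per array.

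The intensities were taken to log2 without an offset, since all were above 0. The 62 control probe sets were left out of the tests. Probe sets were kept when their signal exceeded the array's median on at least 3 of the 6 arrays, which left 27618. The comparison was fitted with limma (lmFit with 1 mean per group, eBayes with trend = TRUE), and p-values were adjusted by the Benjamini-Hochberg method over the probe sets kept. All tests were two-sided. Probe sets were named through the platform's annotation, which can be old, with symbols updated through Entrez identifiers in the RefSeq gene table of GRCh38.p14. Of the 54613 other probe sets, 41091 had 1 gene symbol, 1801 had several and 11721 had none listed. Of those with 1 symbol, 54 kept the array's name. Of the 892 probe sets past the threshold, 704 named 1 gene. No gene was named from a probe set with several genes, except that the CT45 probe sets are given as a family. The sources used here give no genome build, so no coordinates are printed. Each gene was represented by its kept probe set with the highest mean log2 signal, and p-values were adjusted over these 11895 genes. Where all other kept probe sets of a named gene past the threshold differed clearly less from 0 or in the opposite direction, their values are given.

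Before the data were examined, 44 gene lists were fixed, covering signalling pathways, stress and metabolic responses, cell cycle, airway and other lineages, and markers of other cell types. The 38 with at least 5 tested members were compared with the remaining genes by limma's camera with a preset correlation of 0.01, and also with an estimated correlation and with fry. With an estimated correlation camera tests on the 4 residual degrees of freedom of the fit, which alone raises its p. A further description set each list's median against 10000 random lists matched on mean expression in 20 bins. The brightest bin held 35 of the 36 ribosomal protein genes and had a mean log2 signal of 13.82, against 14.75 for that list, so its range is no close match. Named genes followed a rule fixed at the same time. The CT45 probe sets came first, then the 12 largest increases and the 12 largest decreases among genes with an adjusted p under 0.05 whose 3 overexpression arrays all lay on one side of the 3 negative ones, and then up to 4 members of each list with the largest differences among those past the threshold. Where none passed, 1 or 2 members with the smallest p are given as values. Genes named LOC or by an open reading frame, XIST and Y-linked genes were skipped among the 24. Errors are SDs over 3 arrays or limma's standard errors. A group mean below the array median was treated as a dim value, and the fold was then given against the array median as "at least".

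The fit was tested on simulated arrays with the real means and spread, in which 200 genes of the comparison were changed. Of the changed genes tested, 53.0% of those changed 1.5-fold, 78.5% of those changed 2-fold and 98.4% of those changed 4-fold were recovered among 11776 genes, all in the right direction. Of 160 calls, 12 (7.5%) were false, above the 5% that the adjustment aims at. A list shifted by 0.3 on the log2 scale was called, and 0 other lists and, in arrays with no change, 0 genes were called. The noise was drawn separately for each probe set, so simulated genes were uncorrelated. In the real arrays the estimated correlation within a list reached 0.616, for ribosomal proteins. False list calls under such correlation were therefore not tested.

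Alternatives were quantile normalization, centring on the array median, no filter and a filter at the 75th percentile, an offset of 32 before log2, no variance trend, robust eBayes, the replicate number as a block, the mean of a gene's probe sets, no probe sets ending in _x_at or _s_at, and leaving out each array in turn. Cyclic loess and the actin 3'/5' ratio as a covariate were added after the data were seen. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.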

Results

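Gene expression was measured in NCI-H292, a human lung cancer cell line with mucoepidermoid features, after stable transfection. The CT45A1 overexpression group had received a construct of CT45A1 joined to the fluorescent protein Venus, and the CT45A1 negative group had received the Venus vector. CT45A1 is a cancer/testis antigen, a gene of a family on the X chromosome whose transcripts are normally found mainly in testis and reappear in some tumours. Each group had 3 replicates, each on 1 array. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical. The values were MAS5 signals, a linear intensity per probe set, and differences are given on the log2 scale as overexpression minus negative. The median signal per array was 83.4, 82.0 and 79.2 in the overexpression group and 72.6, 72.9 and 75.6 in the negative group. The number of arrays limits the precision of every comparison below.

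The first comparison asked whether CT45 transcripts were higher in the cells labelled as overexpressing. Signal was higher on all 3 overexpression arrays at both CT45 probe sets. The brighter one gave signals of 518, 700.1 and 445 with CT45A1, against 23.1, 15.8 and 1.95 without it. The dimmer one gave 154, 179 and 207 against 2.27, 36.3 and 22.04. The log2 differences were 5.93 (SE 0.78, adjusted p = 0.00539) and 3.87 (SE 0.90, adjusted p = 0.0468), with n = 3 per group in limma. Every negative array lay below its own array median at these probe sets, so the group means set against the array median give folds of at least 7.38 and at least 2.42. Each probe set is annotated to 9 CT45 genes, so CT45A1 could not be told apart from its relatives. Probe sequences were not used here, so it stays open whether these probe sets target the part of CT45A1 that the construct carried, and the signal could not be assigned to the construct or to the cells' own CT45 genes. Without the variance trend the adjusted p was 0.0716 and 0.144, at the same differences. With the actin 3'/5' ratio as a covariate the differences were 2.98 and 4.56 (limma adjusted p = 0.141 and 0.189). For the dimmer probe set the adjusted p was also 0.0611 after quantile normalization, 0.0573 after cyclic loess and 0.073 without a filter on dim probe sets, within a range of 0.00552 to 0.189 over 12 alternatives.

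**Figure D1:**
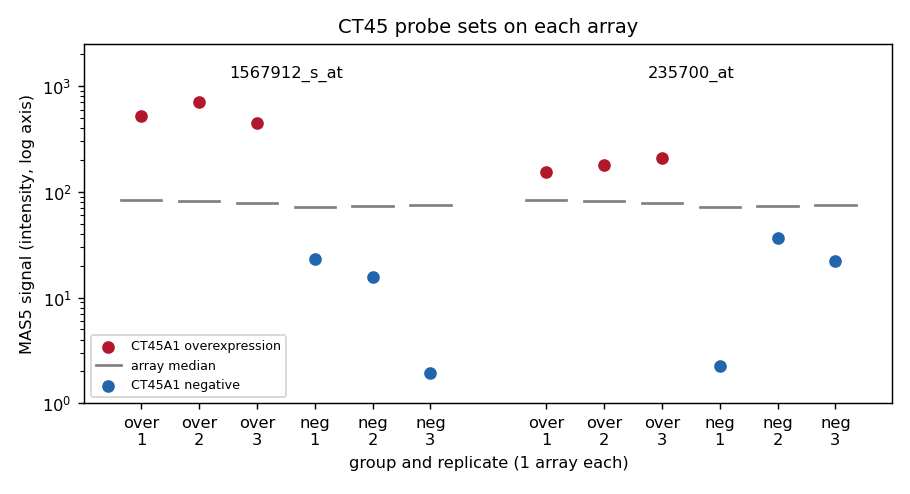
MAS5 signal (log axis) of the brighter (left) and the dimmer (right) CT45 probe set on each of the 6 arrays, with the array's median as a grey line. All 3 overexpression arrays lie above their median and all 3 negative arrays lie below it, at signals from 1.95 to 36.3.

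The main comparison asked which transcripts differed between the groups. TCIM, CYP24A1 and several interferon-induced genes were among the largest increases with CT45A1, and TNKS2, CTSZ and ESM1 were the largest decreases. Of 11895 genes tested, 456 differed at an adjusted p under 0.05, with 231 higher and 225 lower in CT45A1 overexpression. Of these, 47 changed at least 2-fold, 31 upward and 16 downward. At the level of probe sets, 892 of 27618 differed, 522 upward and 370 downward. All 456 genes had their 3 overexpression arrays on one side of the 3 negative arrays. Over all genes tested, 27.2% were separated in that way, against the 10% that chance gives for 3 against 3. An unadjusted p under 0.05 was reached by 2488 genes.

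The largest increase was in TCIM, an activator of Wnt/beta-catenin signalling also known as C8orf4, by 2.39 on the log2 scale (SE 0.34, adjusted p = 0.00571), from a mean log2 signal of 7.08 ± 0.61 to 9.48 ± 0.64 (SD, n = 3). CYP24A1, the enzyme that inactivates vitamin D hormone, rose by 2.14 (SE 0.16, adjusted p = 0.000216), from 7.32 ± 0.04 to 9.46 ± 0.31. COL1A1, a chain of type I collagen, rose by 1.49 from 10.09 to 11.58, while its 3 other probe sets differed by 0.20 to 1.43. C1S, a complement protease, rose by 1.30 from 9.22 to 10.53. RPPH1, the RNA component of ribonuclease P, rose by 1.34 from 6.87 to 8.21, and which form of it the 3' labelling captured was not tested. IFI44L, IFI27, IFIT1, MX1 and OAS2, all induced by interferon, made up 5 of the 12 largest increases. CYP4F2 and CAPN15 rose by 2.24 and 2.21 from negative means of 4.33 and 4.44 to 6.57 and 6.66. Their negative means lay below the array median, against which their folds were at least 1.29 and at least 1.37, and they passed in 5 of 13 and 4 of 14 alternative settings. CYP24A1 and COL1A1 passed in all 18 and 17 alternatives they entered. RPPH1, C1S and OAS2 lost the call when some single arrays other than negative replicate 3 were left out, with the highest adjusted p without overexpression replicate 2, at 0.121, 0.145 and 0.0698.

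TNKS2, a poly-ADP-ribosylating tankyrase, fell by 2.19 on the log2 scale at its brightest probe set, from 11.08 to 8.89 (SE 0.17, adjusted p = 0.000216), the largest decrease. Its other 2 probe sets differed by -0.34 and 0.03. CTSZ, a lysosomal cysteine protease, had the smallest adjusted p of all genes, 2.88e-06, and fell by 1.86 (SE 0.08) from 11.29 ± 0.04 to 9.42 ± 0.05 (SD, n = 3). ESM1, a proteoglycan secreted by endothelial and some tumour cells, fell by 1.63 from 8.85 to 7.23. PIP5K1A, a phosphoinositide kinase, fell by 1.55 from 10.39 to 8.85. MMP1, an interstitial collagenase, fell by 1.42 from 10.45 to 9.03. LMNB1, a nuclear lamin, fell by 1.37 from 11.23 to 9.87, and the chemokine CXCL3 fell by 1.35 from 10.34 to 8.99. COL8A1, a short-chain collagen, fell by 1.40 from 8.34 to 6.94. CDH11, a mesenchymal cadherin, fell by 1.31 from 8.40 to 7.09, with -0.30 at its other probe set, and differed by -0.81 (adjusted p = 0.203) with the mean of its probe sets. FAM181B and EREG fell by 1.56 and 1.26 from 7.48 and 7.45 to means of 5.92 and 6.19 below the array median, against which their folds were at least 2.18 and at least 2.14. STK16 fell by 1.26 from 9.13 to 7.86 at its brightest probe set. Its other probe set differed by 1.19 in the opposite direction (SE 0.65, limma adjusted p = 0.330), from a negative mean of 5.998 below the array median. The mean of both STK16 probe sets differed by -0.04 (adjusted p = 0.968). TNKS2, CTSZ, PIP5K1A and CXCL3 passed in all 17, 17, 17 and 18 alternatives they entered. ESM1, FAM181B, COL8A1, CDH11 and EREG lost it when some single arrays other than negative replicate 3 were left out. The highest adjusted p was 0.0716 for ESM1 and for FAM181B, without overexpression replicate 2, and 0.109, 0.109 and 0.115 for COL8A1, CDH11 and EREG, without negative replicate 1.

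**Figure D2:**
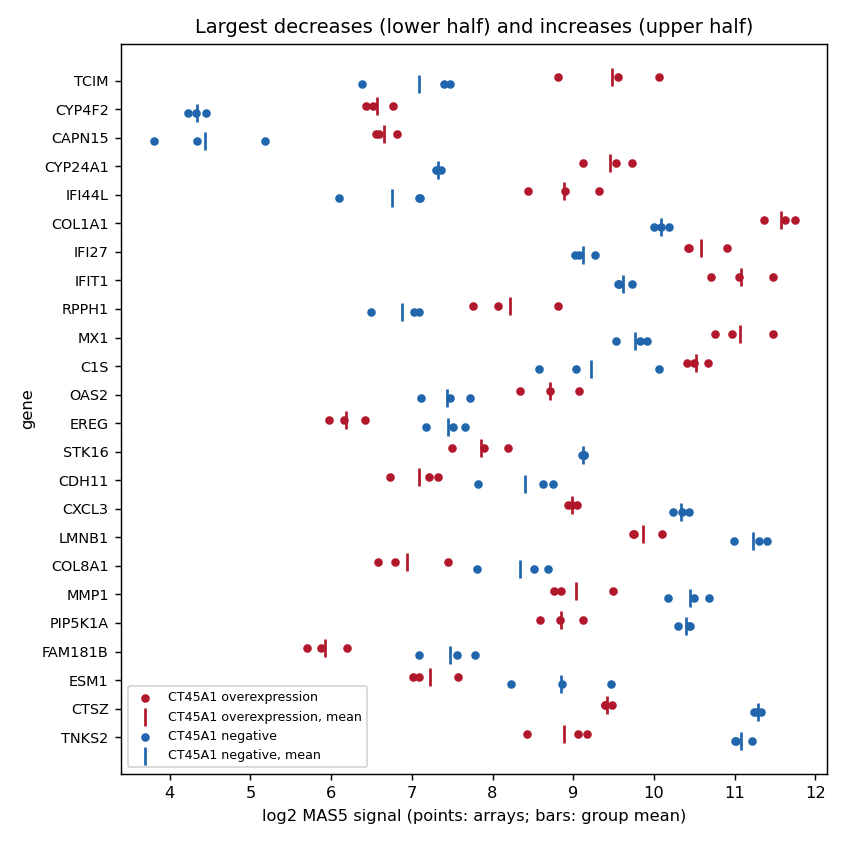
Log2 MAS5 signal on each array (points) and group means (vertical bars) for the 12 largest increases (top) and the 12 largest decreases (bottom). For every gene the 3 overexpression arrays lie on one side of the 3 negative arrays, as for CTSZ at means of 9.42 and 11.29.

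The gene count depended on the variance model and on single arrays. Without the variance trend 11 genes passed, and without probe sets ending in _x_at or _s_at 311 passed. Leaving out overexpression replicate 1, 2 or 3 gave 138, 91 or 297 genes, and leaving out negative replicate 1, 2 or 3 gave 121, 177 or 575. The corresponding counts of genes changed at least 2-fold were 25, 23 and 38, then 27, 31 and 85. The upward and downward split was 174 and 471 after centring each array on its median, against 231 and 225 as deposited. Among genes changed at least 2-fold it was 18 and 21 after quantile normalization, against 31 and 16.

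Interferon-stimulated genes were higher with CT45A1. Of 37 members tested, 22 rose, none fell and 15 did not pass, and all 37 differences were above 0. Adjusted over the list alone, 30 rose. The list's median difference was 0.644, against a 95% range of -0.057 to 0.092 for random lists matched on mean expression. IFI44L rose by 2.13 (SE 0.30) from 6.76 to 8.89, IFI27 by 1.47 (SE 0.14) from 9.12 to 10.59, IFIT1 by 1.46 (SE 0.16) from 9.62 to 11.08 and MX1 by 1.31 (SE 0.17) from 9.76 to 11.06. The camera test gave an adjusted p of 1.80e-24 with its preset correlation and an adjusted p of 0.275 with an estimated correlation. The list's mean log2 signal was 10.34, 10.09 and 9.94 on overexpression replicates 1, 2 and 3, and 9.45, 9.48 and 9.34 on the negative ones. The actin 3'/5' signal ratio, a sign of RNA integrity and of labelling length, was 1.42, 1.49 and 1.55 on the former and 1.70, 1.64 and 1.91 on the latter. With that ratio as a covariate the list's median was 0.318 and the list still passed, while IFI44L, MX1 and OAS2 differed by 0.86, 0.67 and 0.48 (adjusted p = 0.151, 0.0954 and 0.388).

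**Figure D3:**
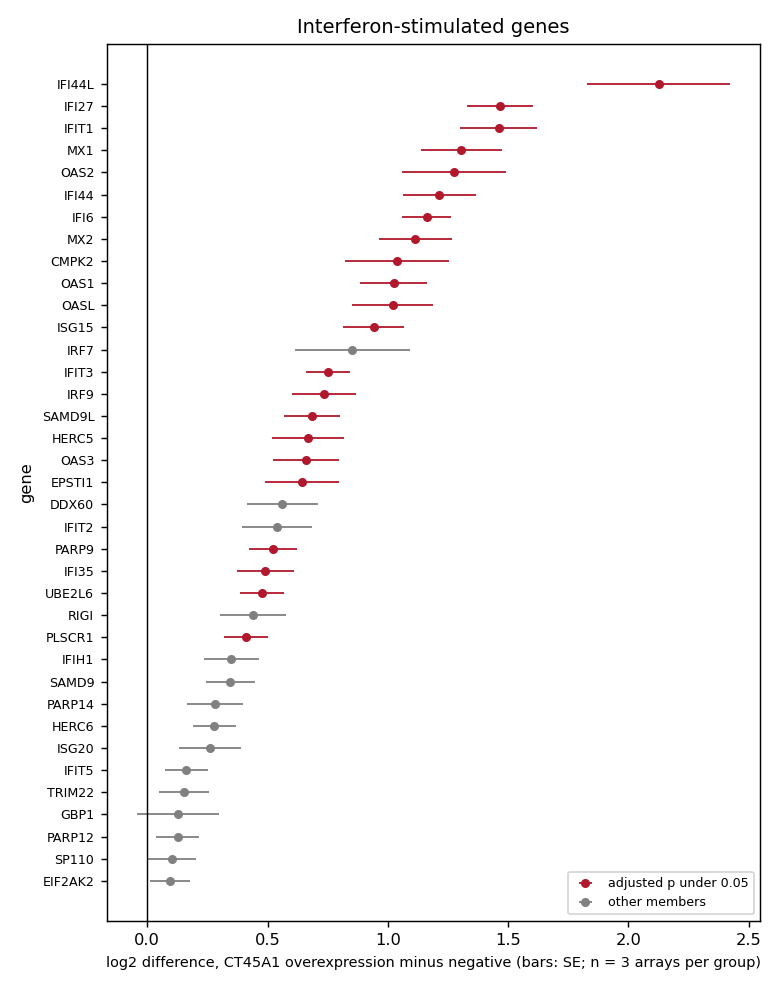
Log2 difference (overexpression minus negative) of the 37 interferon-stimulated genes tested, with its SE, from 3 arrays per group. All 37 points lie above 0, up to 2.13 for IFI44L, and the 22 with an adjusted p under 0.05 are in red.

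Antigen presentation genes changed in both directions. Of 23 tested, 4 rose and 2 fell, or 6 and 4 adjusted over the list alone, and the camera adjusted p was 0.487, upward, with a median of 0.007 and a mean of -0.008. HLA-G and HLA-F, class I molecules, rose by 0.54 and 0.38, and the other HLA-G probe sets differed by 0.05 to 0.38. All probe sets of these genes end in _x_at and can match several transcripts, so a rise of HLA-G itself was not told apart from its relatives. HLA-B and HLA-C, also class I, rose by 0.37 and 0.29. PDIA3, a chaperone of class I assembly, fell by 0.78 at its brightest probe set with 0.01 and 0.06 at its others, and TAP2, part of the peptide transporter, fell by 0.40, with -0.25 and 0.18 at its others. Among NF-kB targets and inflammatory cytokines, 2 of 27 rose and 6 fell, or 4 and 7 adjusted over the list alone, with a camera adjusted p of 0.663. CXCL3 fell by 1.35, PTGS2, the inducible cyclooxygenase, by 0.84 and the chemokine CXCL1 by 0.72, while TNFAIP2 rose by 0.75, with 0.26 at its other probe set. The list's median, 0.194, differed in sign from its mean, -0.003, and from the direction of the test.

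The list of ERK pathway output genes passed downward with members on both sides of 0. Of 28 tested, 15 lay below 0 and 13 above, 6 fell and none rose, or 10 and 3 adjusted over the list alone. Those 3, ETV1, FOS and JUNB, named after their values were seen, differed by 0.96, 0.47 and 0.31 (adjusted p = 0.122, 0.165 and 0.149 over all genes). FOSL1, an AP-1 subunit, fell by 0.97 (SE 0.14) from 9.81 to 8.85, ETV5 by 0.69 from 10.27 to 9.58, and the ERK phosphatases DUSP4 and DUSP6 by 0.64 and 0.58. The list's median was -0.111, with a camera adjusted p of 0.024, and an adjusted p of 0.275 with an estimated correlation. The adjusted p was 0.0617 after quantile normalization, 0.112 without probe sets ending in _x_at or _s_at, with a median of -0.084, and 0.0677 without negative replicate 2, with a median of -0.073. The median was -0.177 without negative replicate 3 (adjusted p = 0.0286), and without a filter on dim probe sets it was 0.003 while the test still ran downward (adjusted p = 0.0204). Of 10 EGFR ligands and receptors, 3 fell and none rose, with the same counts adjusted over the list alone and a camera adjusted p of 0.353. These were the ligands EREG, NRG1 and TGFA, which fell by 1.26, 0.75 and 0.54.

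The list of TGF-beta targets, which also holds pathway members such as TGFB1 and TGFBR1, was shifted upward, and pathway activity was not tested. Of 20 tested, 15 lay above 0 and 5 below, 5 rose and none fell, with the same counts adjusted over the list alone, and the median was 0.224 (camera adjusted p = 0.00117, and adjusted p = 0.399 with an estimated correlation). CCN2, a matricellular growth factor, rose by 0.90 (SE 0.13) from 9.98 to 10.88, LTBP3, which binds latent TGF-beta, by 0.90 from 8.91 to 9.81, with 0.42 at its other probe set, ID3 by 0.60 and BHLHE40 by 0.44. Without probe sets ending in _x_at or _s_at, where LTBP3 was not tested, the list's adjusted p was 0.0735, and with the actin ratio as a covariate the list's median was 0.046 (adjusted p = 0.914). YAP/TEAD targets had a median of -0.158 (camera adjusted p = 0.0287, and adjusted p = 0.574 with an estimated correlation). Of 22, 17 below 0 and 5 above, CCN2 rose and FJX1 and AXL fell by 0.40 and 0.29, with 1 and 5 adjusted over the list alone, and the other AXL probe set differed by -0.06. That list had an adjusted p of 0.137 after quantile normalization, and a median of -0.081 without negative replicate 2 (adjusted p = 0.229). Its mean log2 signal overlapped between the groups, at 11.46, 11.51 and 11.42 against 11.54, 11.64 and 11.47. Of 11 Wnt targets only DKK1, a secreted Wnt inhibitor, passed, and it fell by 0.61 (list adjusted p = 0.0847). Of 15 Notch pathway genes only the ligand JAG2 passed, and it rose by 0.45 (list adjusted p = 0.654). Adjusted over the list alone, 1 Wnt target rose and 4 fell, and 2 Notch genes rose and 1 fell.

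The stem cell associated list was shifted downward, with a median of -0.334 over 9 tested, 8 below 0 and 1 above (camera adjusted p = 0.00117, and adjusted p = 0.248 with an estimated correlation). Of these, 2 fell, or 4 adjusted over the list alone, and none rose. The 2 were ALDH1A3, an aldehyde dehydrogenase, and ITGA6, a laminin receptor subunit, by 0.37 and 0.33, and the other ALDH1A3 probe set differed by -0.17. Without a filter on dim probe sets the median was 0.109 (adjusted p = 0.208). Of 5 genes that earlier work tied to CT45A1 in breast cancer cells, 2 were kept by the filter on dim probe sets and neither passed in limma, where 0 had an unadjusted p under 0.05. CXCR4 differed by 0.83 (SE 0.40, limma adjusted p = 0.265), and its arrays overlapped between the groups. Its negative mean of 5.84 lay below the array median, and its overexpression mean lay 1.38-fold above that median. Without the filter 1 of the 5, KIT, had an unadjusted limma p under 0.05 (adjusted p = 0.217). Its means of 3.85 with CT45A1 and 1.40 without it were both dim, while TWIST1 and SULF2 lay below 0. SULF2 differed by -0.12 (SE 0.07, adjusted p = 0.304), and by 0.004 with the mean of its probe sets. Of 26 other cancer/testis antigens on the array, 2 were bright enough to test, and neither passed, although both had an unadjusted p under 0.05. MAGEA12 differed by -0.73 (adjusted p = 0.0623, and 0.0357 after quantile normalization) and MAGEA6 by -0.54 (adjusted p = 0.236).

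Matrix and adhesion genes changed in both directions, and none of their lists passed the camera test. Of 26 mesenchymal and EMT genes, 3 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.365). COL1A1 and CCN2 rose, TGFBI, a secreted matrix protein, rose by 0.36, and CDH11 fell. Of 36 epithelial junction and identity genes, LLGL2, a polarity protein, rose by 0.63, and its other probe set differed by 0.01, while KRT18, a simple epithelial keratin, fell by 0.25, the same counts adjusted over the list alone (list adjusted p = 0.365). LLGL2 passed in 2 of 17 alternatives and KRT18 in 9 of 17. Of 25 matrix proteases and inhibitors, MMP15 rose by 1.25 and MMP1 and ADAMTS1 fell by 1.42 and 0.95 (list adjusted p = 0.0847), and 2 rose and 4 fell adjusted over the list alone. The other ADAMTS1 probe set differed by -0.33. MMP15 rose from a negative mean of 6.356, near the negative group's mean log2 array median of 6.204. It passed in 6 of 16 alternatives and differed by as little as 0.536 in them. Of 19 integrins and laminins, LAMA5 rose by 0.79 and ITGA6 fell by 0.33 (list adjusted p = 0.267), and 2 rose and 1 fell adjusted over the list alone. LAMA5 and ITGA6 passed in 12 of 17 and 8 of 18 alternatives. The medians of the mesenchymal, epithelial and integrin lists, 0.113, 0.054 and 0.091, lay above the upper ends of the ranges of matched random lists, 0.094, 0.032 and 0.039, and the integrin list passed after cyclic loess (adjusted p = 0.0344).

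The list of replication-dependent histones was shifted upward. Of 11 tested, 4 rose, or 6 adjusted over the list alone, 7 were not called, all 11 differences were above 0, and the median was 0.464 (camera adjusted p = 4.28e-06, and adjusted p = 0.223 with an estimated correlation). H1-2, a linker histone, rose by 0.68 (SE 0.07) from 11.12 to 11.80, H2BC21 by 0.64, H2BC12 by 0.46 and H2AC6 by 0.44. Which forms of these histone transcripts the 3' labelling captured was not tested, so a rise of the replication-dependent forms themselves stays open. Of 53 G2/M and mitosis genes 0 passed in limma, 6 had an unadjusted p under 0.05, and the list's adjusted p was 0.729. Of 55 S phase and replication genes, DTL and GINS2 fell by 0.46 and 0.45, with 2 also adjusted over the list alone (list adjusted p = 0.0518), and the other DTL probe set differed by -0.20. Among 9 CDK inhibitor and senescence genes, LMNB1 and the chromatin proteins HMGA2 and HMGA1 fell by 1.37, 0.87 and 0.46, and 1 rose and 3 fell adjusted over the list alone (list adjusted p = 0.194). The other 2 probe sets of HMGA2 differed by -0.31 and -0.01, and HMGA2 lost its call without probe sets ending in _x_at or _s_at (adjusted p = 0.467) and, at -0.40, with the mean of its probe sets (adjusted p = 0.149). Of 29 p53 targets, 3 fell, also adjusted over the list alone (list adjusted p = 0.148). These were the pro-apoptotic BAX, by 1.19 (SE 0.20) from 9.46 to 8.27, CCNG1 by 0.52 and PLK2 by 0.36. Of 24 apoptosis regulators, CASP8 rose by 0.37 and MCL1 fell by 0.36 at its brightest of 6 probe sets, the same counts adjusted over the list alone (list adjusted p = 0.175).

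Among stress and metabolic lists, the ATF4 and amino acid response list was shifted upward, with a median of 0.162 over 30 tested, 23 above 0 and 7 below (camera adjusted p = 0.00968, and adjusted p = 0.460 with an estimated correlation). Of these, 3 rose, or 4 adjusted over the list alone. ATF3, a stress-induced transcription factor, rose by 0.87 (SE 0.09) from 9.04 to 9.90, PHGDH, the first enzyme of serine synthesis, by 0.52, and SLC3A2, an amino acid transporter subunit, by 0.48. Without probe sets ending in _x_at or _s_at the list's median was 0.052 (adjusted p = 0.282), without negative replicate 2 it was 0.101 (adjusted p = 0.0677), and without overexpression replicate 3 it was 0.079 (adjusted p = 0.0126). The adjusted p was 0.0802 with fry. Oxidative phosphorylation genes had a median of -0.076, inside the -0.125 to -0.030 of matched random lists (camera adjusted p = 0.0123, adjusted p = 0.460 with an estimated correlation, and 0.811 after quantile normalization). Of 34, 25 below 0 and 9 above, SDHA fell by 0.42 and NDUFV1 rose by 0.38, with the same counts adjusted over the list alone. That median was 0.028 after cyclic loess, and leaving out overexpression replicate 1 or negative replicate 3 gave an adjusted p of 0.0602 or 0.0596. The other lists of this kind did not pass as deposited. The unfolded protein response and heat shock lists passed after quantile normalization (adjusted p = 0.0398 and 0.0453) and after cyclic loess (adjusted p = 0.0192 and 0.0296), upward. PDIA4 and HYOU1 rose by 0.33 and 0.29 among 23 unfolded protein response genes, with 2 up and 1 down adjusted over the list alone (list adjusted p = 0.296), and without probe sets ending in _x_at or _s_at PDIA4 differed by -0.001. HSPB1, HSPB8 and HSPA4 rose by 0.45, 0.44 and 0.28 among 20 heat shock genes, with 3 up and 1 down adjusted over the list alone (0.516), while the other HSPB8 probe set differed by -0.12. PGD rose by 0.67 among 25 NRF2 targets (0.663), GPI rose by 0.33 among 36 hypoxia and glycolysis genes (0.969), and DHCR7 fell by 0.52, with -0.07 at its other probe set, among 25 cholesterol genes (0.928). CYP24A1 was the only gene to pass among 15 xenobiotic metabolism genes (0.452). WIPI1 rose by 0.57 and CTSZ fell among 32 autophagy and lysosome genes, with 3 up and 1 down adjusted over the list alone (0.365). For the NRF2, hypoxia, cholesterol and xenobiotic lists the counts were the same adjusted over the list alone. The hypoxia list had a median of -0.001, a mean of 0.028 and an upward test, and the cholesterol list had a median of 0.015, a mean of 0.052 and a downward test.

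The airway secretory and mucin list passed upward as deposited, but its arrays overlapped between the groups. Its median was 0.328 over 17 tested, 16 of them above 0 (camera adjusted p = 0.00968, and adjusted p = 0.483 with an estimated correlation). The list's mean log2 signal was 8.76, 8.94 and 9.07 on the overexpression arrays and 8.56, 8.11 and 8.91 on the negative ones, and the mean difference of 0.398 was smaller than the negative group's SD of 0.404. None passed singly in limma, also adjusted over the list alone, and 4 had an unadjusted p under 0.05, including MUC4 with 0.26 (adjusted p = 0.143) and MUC16 with 0.59 (adjusted p = 0.15, and 0.00908 without negative replicate 3). Without negative replicate 2, the lowest array, the list's median was 0.183 (adjusted p = 0.245), without negative replicate 3 it was 0.507 and the list still passed, and without a filter on dim probe sets it was 0.256 (adjusted p = 0.173). The adjusted p was 0.194 with fry. S100A2 and SFN fell by 0.38 and 0.28 among 24 squamous and basal genes (list adjusted p = 0.729), and LAMP3 rose by 0.60 among 7 alveolar and ciliated genes (0.449), with the same counts adjusted over the list alone. The squamous list's median and mean, 0.017 and 0.038, differed in sign from its downward test. No neuroendocrine gene of 6 passed in limma, where 1, TUBB3 with 0.29, had an unadjusted p under 0.05 and an adjusted p of 0.0355 after quantile normalization, and 1 rose adjusted over the list alone (list adjusted p = 0.948). Markers of other cell types gave no leukocyte call among 5 tested in limma (list adjusted p = 0.969 downward with a median of 0.044, 0 with an unadjusted p under 0.05), no endothelial call among 3 (1 with an unadjusted p under 0.05, CDH5 with 0.79), and no erythroid call among 2 (0 with an unadjusted p under 0.05). Of 2 fibroblast markers tested, COL1A1 rose.

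The ribosomal protein, ribosome biogenesis and splicing lists were slightly lower. Ribosomal protein genes had a median of -0.155, with all 36 below 0, and 1 of them, RPS23, fell by 0.26, with -0.01 at its other probe set, or 6 adjusted over the list alone (camera adjusted p = 7.71e-10, and adjusted p = 0.460 with an estimated correlation). After quantile normalization the median was -0.018 (adjusted p = 0.466). Ribosome biogenesis genes had a median of -0.119 over 31, 20 below 0 and 11 above, and WDR43 fell by 0.47, with 2 rising and 10 falling adjusted over the list alone (camera adjusted p = 0.0261, adjusted p = 0.275 with an estimated correlation, and 0.133 after quantile normalization). Without overexpression replicate 1 or negative replicate 2 its adjusted p was 0.0514 or 0.0677. Splicing and RNA-binding genes had a median of -0.079 over 37, 28 below 0 and 9 above, inside the -0.114 to -0.014 of matched random lists, and SRSF1 fell by 0.27, with -0.25 to 0.44 at its 7 other probe sets, or 4 fell adjusted over the list alone (camera adjusted p = 0.0077, adjusted p = 0.248 with an estimated correlation, and 0.316 after quantile normalization). The epigenetic and DNA methylation list had 0 of 27 genes past the threshold in limma and 6 with an unadjusted p under 0.05 (list adjusted p = 0.596).

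In all, 12 of 38 lists passed with camera's preset correlation, 5 upward and 7 downward. With an estimated correlation 0 passed, and 6 had an unadjusted p under 0.05. The higher p-values with an estimated correlation do not measure correlation alone, since that version tests on the 4 residual degrees of freedom. For the histone, stem cell, splicing, ribosome biogenesis and ERK lists the estimate was -0.015, -0.033, -0.026, -0.020 and 0.001, below the preset 0.01. The fry test, which does not compare a list with other genes, called 8, of which 6 were among the 12. The others were CDK inhibitors and senescence, downward (fry adjusted p = 0.0293), and apoptosis regulators, upward (fry adjusted p = 0.0469). Besides the ATF4 and airway lists, fry did not call the TGF-beta (adjusted p = 0.05845), YAP/TEAD (0.206), oxidative phosphorylation (0.105) and ribosomal protein (0.118) lists. Of 20 alternatives, the interferon and histone lists passed in 19 each, the stem cell list in 18, the TGF-beta, ATF4, airway, ribosomal protein and splicing lists in 16 each, the ERK list in 15, and the YAP/TEAD, oxidative phosphorylation and ribosome biogenesis lists in 11 each. Of the 26 lists that did not pass, 9 had a median outside the range of matched random lists. Without negative replicate 2, or without probe sets ending in _x_at or _s_at, 7 lists passed. After quantile normalization 8 passed, 7 upward and 1 downward.

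**Figure D4:**
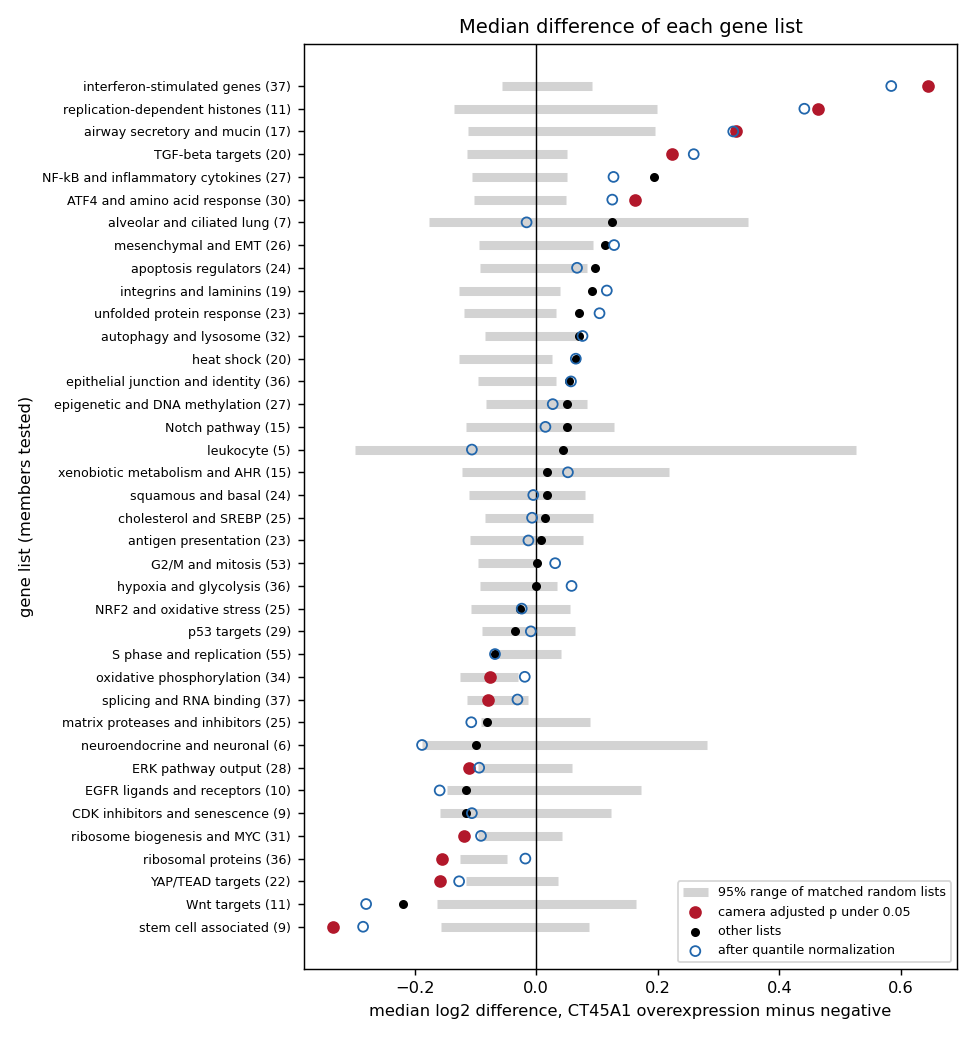
Median log2 difference (overexpression minus negative) of the 38 gene lists tested, as deposited (filled points, red where the camera adjusted p was under 0.05) and after quantile normalization (open circles), with the 95% range of random lists matched on mean expression (grey bars). Interferon-stimulated genes lie at 0.644 and 0.584 and histones at 0.464 and 0.441, while ribosomal proteins move from -0.155 to -0.018.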

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

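The tests in this part were chosen after the results they bear on had been seen, although quantile normalization and leaving out single arrays had been planned as alternatives.

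Of the control probe sets, which entered no comparison, the 5'/3' ratios of GAPDH and actin separated the groups. The spike and hybridization controls overlapped between the groups, with exact permutation p from 0.30 to 0.70. Overexpression replicate 3 was the lowest array for BioB, BioC, BioDn and CreX, at 681 for BioB against 1152 to 1242 on the other arrays. Its ThrX signal, 440, was the highest. What set this array apart was not tested. The 5'/3' signal ratio of GAPDH averaged 0.995 ± 0.035 with CT45A1 and 0.905 ± 0.051 without it (SD, n = 3), and its lowest overexpression array, 0.963, lay above the highest negative one, 0.950. The 5'/3' ratio of actin averaged 0.674 ± 0.029 and 0.573 ± 0.044, with 0.645 above 0.608. The two-sided exact permutation p was 0.10 for each ratio, the smallest that 3 against 3 arrays allow.

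The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, the 1 with the most calls in each case, gave 892 probe sets, 456 genes, 47 genes changed at least 2-fold and 12 lists. The highest of the other splits gave 0, 0, 0 and 9. In limma those other splits had 167 to 887 genes with an unadjusted p under 0.05, against 2488 in the real one.

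Interferon-stimulated genes were higher with CT45A1. Scaling that depends on intensity is argued against, since the list's median was 0.584 after quantile normalization, above the 0.067 that bounds 95% of matched random lists. A single divergent array is argued against too, since the lowest median with 1 array left out was 0.515, above the larger within-group SD of 0.199. The difference in RNA 3'/5' ratio cannot be told apart from the group, because the ratio separates the groups: with the actin ratio as a covariate the list mean differed by 0.412 (95% interval -0.140 to 0.963), against 0.699 without it, and the list still passed camera with its preset correlation. An effect of CT45A1, or of the transfected line that carries it, may be the source and stays open, since the labels do not say whether a group holds more than 1 transfected line.

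Ribosomal protein genes were lower with CT45A1, and over all genes the median difference fell from 0.154 in the dimmest of 10 equal groups by mean signal to -0.084 in the brightest. Intensity-dependent scaling cannot be told apart from a change in these genes: after quantile normalization their median was -0.018, but ribosomal protein genes made up 28 of the 46 genes brighter than the list's median signal, so giving all arrays 1 distribution largely fixes that value. A shift shared with other genes of like signal stays open too, since the median of -0.155 as deposited lay below the -0.124 to -0.090 of lists of the 20 nearest other genes, but the list's mean signal of 14.753 lay above the 14.668 to 14.751 of those lists. A difference in RNA 3'/5' ratio cannot be told apart from the group, because the interval spans 0: with the actin ratio as a covariate the list mean differed by -0.154 (95% interval -0.501 to 0.194), against -0.142 without it, and the list still passed camera with its preset correlation. A true fall in abundant transcripts was not tested separately.

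For some genes, probe sets moved differently. Among 6035 genes with at least 2 kept probe sets, the 2 brightest differed in their change for 90 at an adjusted p under 0.05 (limma), including TNKS2 with -2.19 and -0.34 and PDIA3 with -0.78 and 0.01. A dim partner near the floor is argued against as the whole cause. Of the 90, 77.8% (Wilson 95% interval 68.2% to 85.1%) had both probe sets above the 75th percentile of signal. The share of such bright pairs among all 6035 genes was not taken, and the bound of this test was revised after a first run. The share of differing genes was 1.17% with partners within 1 log2 unit and 2.09% with partners over 2 units dimmer. Probe sets that can match several transcripts may contribute, since the odds of an _s_at or _x_at member were 1.98 times those of other genes (95% interval 1.18 to 3.44, Fisher's exact p = 0.00561). A change in transcript isoforms or 3' ends was not tested and stays open.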

How the results depend on the processing

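The alternatives were set before the data were examined, except cyclic loess and the actin 3'/5' covariate, and the cause of a change was not tested unless stated. All 456 genes kept their direction under quantile normalization, centring, cyclic loess, no filter and the actin covariate, and 331, 398, 325, 303 and 145 of them passed again. Direction under centring and no filter says little on robustness. Without a filter each probe set keeps its difference, and centring shifts all differences alike, from a gene median of 0.008 to -0.060. Direction was kept by 314 of 332 without _x_at and _s_at probe sets, 449 of 456 with the mean of probe sets, 454 of 455 without negative replicate 1 and 453 of 455 without negative replicate 2 or 3. Since the arrays of all 456 were separated, leaving out 1 array cannot reverse a gene at the same probe set. Those leave-out counts, where another probe set can come to represent a gene, therefore say nothing on robustness. Probe sets past the threshold numbered 892, against 486 without a filter, where more probe sets were tested, 4 without the variance trend, and 159 to 1171 with 1 array left out. Genes numbered 456, against 11 without the trend, 311 without _x_at and _s_at probe sets, where fewer were tested, and 91 to 575 with 1 array left out. The count of 575, above that with all arrays, came without negative replicate 3. Genes changed at least 2-fold numbered 47, against 21 with the filter at the 75th percentile, 8 without the trend, 195 with the actin covariate, and 23 to 85 with 1 array left out. Lists numbered 12, against 7 without _x_at and _s_at probe sets, 0 with an estimated correlation, and 7 to 13 with 1 array left out. The brighter CT45 probe set lost its call at 5.930 without the trend and at 2.978 with the actin covariate, and kept it in 10 of 12 alternatives. The dimmer one lost it at 3.757 after quantile normalization, 3.871 without a filter or without the trend, 3.726 with cyclic loess and 4.564 with the actin covariate. Of genes and lists past the threshold, reversed were PDIA4 at -0.001 and HSPB8 at -0.118 without _x_at and _s_at probe sets, SRSF1 at 0.037 with the mean of probe sets, the medians of the ERK list at 0.003 and the stem cell list at 0.109 without a filter, and that of oxidative phosphorylation at 0.028 with cyclic loess. Of named genes not past it, SULF2 changed sign at 0.004 with the mean of probe sets, AURKA at 0.085 without _x_at and _s_at probe sets, LAPTM5 at 0.097 with the actin covariate, and AHSP at 0.299 with that covariate and 0.050 without overexpression replicate 1, in a range from -0.844 with 1 array left out. Of the other values of named genes under alternatives, 1340 stayed on their side of the threshold, 439 lost the call and 10 gained it, and of those of lists 183 stayed and 54 lost the call. The interferon and histone lists passed in 19 of 20 alternatives each, all but the estimated correlation.

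The replicate number showed no clear pairing of the arrays, as deviations of same-numbered arrays correlated at -0.011, -0.007 and 0.103, and not every array correlated best with its own number. With the number as a block 536 genes, 1189 probe sets, 46 genes changed at least 2-fold and 13 lists passed. Without it the counts were 456, 892, 47 and 12. Variation shared by same-numbered arrays is therefore not excluded. Without detection calls, dim signals cannot be set against background.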

Other observations

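All tests in this part, and the genes named, were chosen after the values had been seen.

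Some genes outside the fixed lists are given singly here, without a test of any group they belong to. LTBR, the lymphotoxin beta receptor, fell by 1.21 (SE 0.13, adjusted p = 0.00129) from 9.99 to 8.78. SLIT2, a secreted guidance factor, fell by 0.95, IRS1, the insulin receptor adaptor, by 0.80, VEGFC, a lymphangiogenic ligand, by 0.78, NRP1, a semaphorin and VEGF co-receptor, by 0.77, and TGFBR2, the type II TGF-beta receptor, by 0.62. EFNA1, an ephrin ligand, rose by 0.98 (SE 0.11, adjusted p = 0.00214) from 11.24 to 12.22, and MDK, the growth factor midkine, by 0.70. TYK2, a kinase of the type I interferon receptor, rose by 0.70, HELZ2 by 1.16 and ZNFX1 by 0.67.

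The interferon ligands were too dim to test. Of 14 ligands, 13 were measured, 0 passed the filter on dim probe sets, and the highest group mean was 5.74 on the log2 scale. Without that filter 0 of the 13 passed in limma and 1 had an unadjusted p under 0.05.

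A first hypothesis was that the interferon pattern extended to genes led by interferon gamma, such as the GBP family and class II antigen presentation, some of which also stand in the fixed lists. For the 17 such genes tested no shift beyond matched random lists was seen, since their median was 0.128, inside the -0.109 to 0.186 of those lists. Their median lay 0.525 below that of the 36 other interferon-stimulated genes, more than the members' SD of 0.405. The bound of this test was revised after a first run. Some members were dim, such as CIITA at means of 5.31 with CT45A1 and 6.28 without it, so a smaller shift stays open. Among the 17, TAP2 fell and none rose.

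A second hypothesis was that CYP24A1, the classic target of the vitamin D receptor, rose with other targets of that receptor. The median of 15 other targets was 0.016, inside the -0.100 to 0.147 of matched random lists, and members went both ways, with STEAP4 rising and VDR falling by 0.56, so this test leaves the hypothesis open.

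Another hypothesis was that 1 line had gained or lost a whole chromosome. Over 22 autosomes and X, the largest absolute chromosome median relative to all genes was 0.056, on chromosome 19, under the bound of 0.2 set for such a change, and the smallest camera adjusted p was 0.931. Changes of parts of chromosomes, or in a fraction of the cells, were not excluded.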
